A study of Mus musculus with 4 samples.

How the data were processed

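Gene expression was measured in bone marrow stromal cells of C57BL/6 mice that carry green fluorescent protein under the nestin promoter (Nes-gfp). Per the labels, cells negative for CD45, CD31 and Ter119 and positive for the reporter were isolated 10 weeks after transplantation of bone marrow cells. The 3 mice of the MPN group (myeloproliferative neoplasm) had received cells with a mutant JAK2 and the inducible Mx1-cre transgene, and 1 mouse had received control cells. The titles name each sample as a mouse, so each array was taken as 1 mouse.

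Per the labels' protocols and the design text, RNA was isolated with a Picopure kit, amplified with the NuGEN Ovation system, labelled with biotin and hybridised to Affymetrix mouse gene arrays. The deposited values are on a log2 scale and were made by the authors with RMA (robust multi-array average), per the submitters' processing notes. RMA corrects each array for background, normalises the arrays to one distribution and combines the probes of a probe set. It compresses differences near the background and assumes that the arrays share one overall distribution. The version of RMA, the probe set definitions and a genome build are not given in the sources used here, so no coordinates are printed. The deposited log2 values ran from 1.55 to 13.63. Array data have no read depth, and the number of arrays limits the precision.

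The value table holds 35556 probe sets. The platform's gene table gives 1 gene symbol for 21789 of them and several for 1621, and the other 12146 are unnamed here. Of the probe sets with 1 symbol, 21698 were matched by gene identifier to the mouse RefSeq gene table, and 0 symbols changed. Of several probe sets of a gene, the one with the highest mean over the 4 arrays was kept, which left 19938 genes. A background limit of 5.21 was set as the 95th percentile of the mean over arrays of 1196 olfactory and vomeronasal receptor genes, which marrow is not known to use. In either group, 11968 genes had a mean above it. In 134 genes the 3 MPN arrays held identical values, and limma offset their zero variance. A difference from a group under the background limit depends on where background lies, so its size there is uncertain.

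The groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided), with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05 for the adjusted p. The fit has 2 residual degrees of freedom, all from the MPN arrays, and a prior of 1.39 degrees of freedom. The lone control was assumed to vary like the MPN mice, which these data cannot test. SE is the standard error of the difference from this fit, and SD is the spread of the 3 MPN arrays. Genes at least 2-fold apart from the control on each of the 3 MPN arrays were counted as a description of size.

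Before the data were examined, 34 gene lists were fixed, of which 32 had at least 5 measured genes and were tested. The test was limma's camera with a preset correlation between genes of 0.01, adjusted over the lists. It compares a list with the other genes measured. Camera with a correlation estimated from the residuals, and fry, were run as alternatives. Fry asks whether the genes of a list move one way on balance and makes no comparison with other genes. For each list, the genes past the threshold were also counted with p adjusted over the list alone. Each list's median difference was set among those of 10000 random lists of the same size matched on mean expression.

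Named genes followed a rule fixed before the data were examined. It takes the 15 largest differences in each direction, filled up with genes 2-fold apart on each MPN array where too few passed the test. Predicted genes, chemosensory receptor genes and small RNA genes were left out. It adds up to 3 members of each list with the largest difference, and 11 genes chosen for the niche and its signals. Of those 11, 8 had a value, and the others are not reported here.

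The steps were tested on simulated data for this comparison of 3 arrays against 1, over 19938 genes. At the adjusted threshold, 0% of genes with a simulated log2 change of 2 were recovered, 52.24% at a change of 4 and 77.27% at 6, with 7 false calls in all. With no change simulated, 0 genes were called. Of 30 simulated lists, all 5 shifted by 1.5 were called and 0 of the others. The simulated genes were drawn independently of each other. The simulation therefore does not show how often camera calls a list of correlated genes without a group difference. The alternatives left out each MPN mouse in turn, averaged the probe sets of a gene, removed genes under the background limit, and repeated quantile normalisation. Further ones applied cyclic loess, shifted the arrays to one median, changed the variance prior, tested all probe sets, or required a minimum difference. For the lists, members of more than 1 list were left out. Shifting the arrays to one median of the receptor genes was chosen after seeing the data.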

Results

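The study concerned damage to the nerves of the marrow niche in myeloproliferative neoplasm. These arrays compared nestin reporter stromal cells, a population that holds mesenchymal cells supporting blood stem cells, between mice with MPN marrow (n = 3) and a mouse with control marrow (n = 1). The median deposited log2 value over all probe sets was 5.15, 5.16 and 5.09 on the MPN arrays and 5.13 on the control array. Over 19938 genes, Pearson's r across genes was 0.872, 0.886 and 0.882 between MPN arrays. The control array gave 0.813, 0.802 and 0.875 with MPN mice 1, 2 and 3. Genes are not independent replicates, so these values describe the arrays only. The median gene lay 0.179 higher on the MPN arrays than on the control array, and the receptor genes that mark background lay 0.254 higher. Differences below are given as deposited and should be read against that shift.

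Among the genes open to naming, the largest differences were those of Fgf7 and Kitl, which were lower on the MPN arrays, and Xist, which was higher. Fgf7, a fibroblast growth factor made by mesenchymal cells, was at 4.53 ± 0.43 (SD, n = 3) against 10.65 in the control. Kitl, the stem cell factor that blood stem cells need, was at 4.10 ± 0.36 against 10.00, and Phex, a peptidase of bone-forming cells, at 3.95 ± 0.24 against 9.59. Xist, the RNA of the inactive X chromosome, was at 8.97 ± 0.52 against 3.30. Ifitm6 was at 9.96 ± 0.30 against 4.90, and Mmp8, the neutrophil collagenase, at 10.67 ± 0.44 against 5.90.

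None of the genes passed limma's test at the adjusted threshold. The smallest adjusted p was 0.0871, and 2511 genes had an unadjusted p under 0.05, 791 of them higher and 1720 lower in MPN. In size alone, 225 genes were at least 2-fold higher and 1153 at least 2-fold lower on each of the 3 MPN arrays, 1378 together. All 3 MPN arrays lay on one side of the control for 67.8% of genes, where an array picked at random gives 50% on average. Genes of an array move together and the median gene lay 0.179 higher on the MPN arrays, so this share is no test of the group. The other genes of the 15 largest lower differences were Lifr, Cp, Postn, Stox2, Chrdl1, Slitrk6, Mmp13, Plxdc2, Ghr, Slit2, Adgrl2 and Adipoq. Their log2 differences ran from -5.27 for Lifr to -4.76 for Adipoq. The other genes of the 15 largest higher differences were Plekhb1, Chil3, Ly6g, Lcn2, H4c6, Slfn4, Il1f9, Gca, Pglyrp1, Ermn, Ltf and Mobp, from 5.05 for Plekhb1 to 3.91 for Mobp. The standard error reached 2.42 for Mmp13 and 2.21 for Il1f9, whose MPN mice differed widely. The count of genes past the threshold was 97 after cyclic loess and 153 after shifting the arrays to one median of the receptor genes, a setting chosen after seeing the data. The count of genes 2-fold higher was 373 to 378 when any 1 MPN mouse was left out, and without MPN mouse 3 the total was 2134 and the count lower was 1756.

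**Figure D1:**
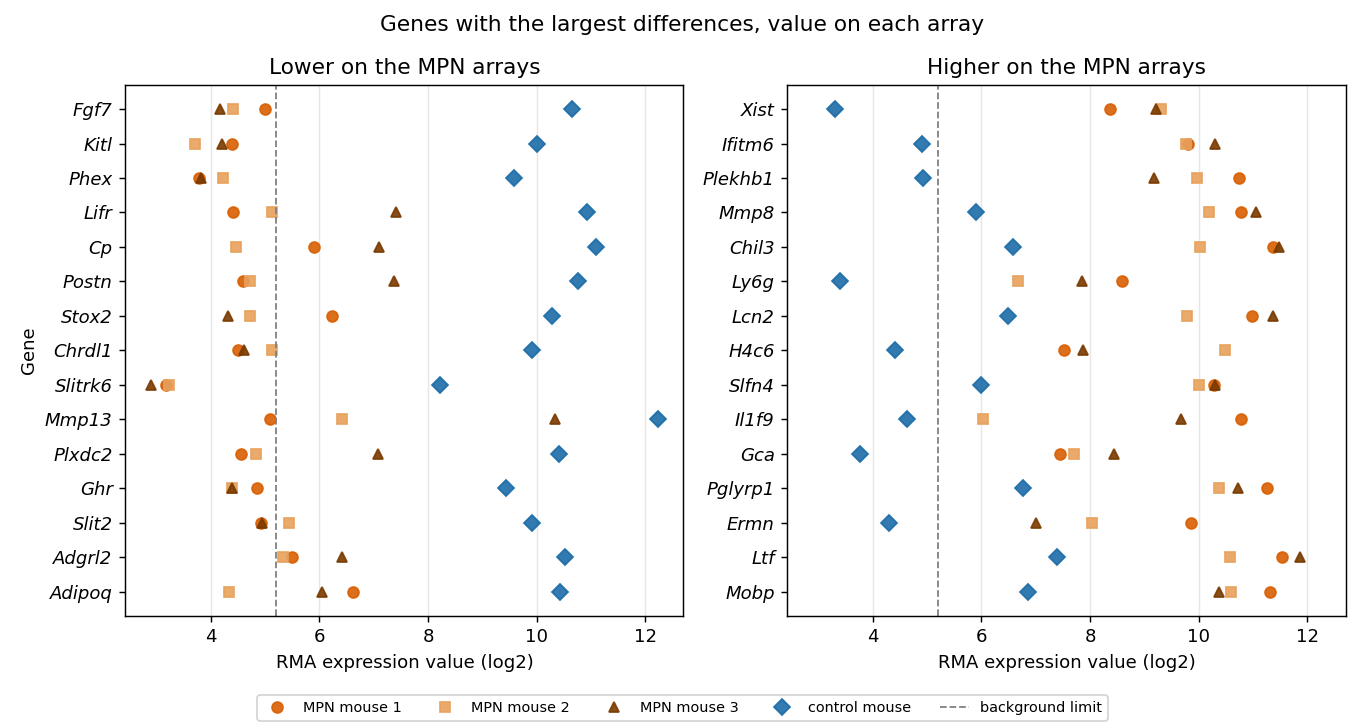
RMA expression value (log2, horizontal axis) of the 15 genes with the largest lower and the 15 with the largest higher differences, 1 point per array; the dashed line is the background limit of 5.21. On the left the control point lies right of every MPN point, and on the right it lies left of every MPN point; Kitl lies under the limit in each MPN mouse and at 10.00 in the control.

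The stem cell niche list fell in MPN, with a median log2 difference of -2.03 over 18 measured genes. Adjusted over the list alone, 12 genes fell and 0 rose, and 0 passed over all genes tested. Kitl (-5.89, SE 0.35) and Fgf7 (-6.12, SE 0.41) were among the 12, as were Angpt1, the angiopoietin ligand of Tie2, at -3.22 (SE 0.42) and Vcam1, an adhesion molecule for blood cells, at -3.74 (SE 1.06). Cxcl12, the chemokine that retains stem cells in marrow, was at 8.93 ± 0.65 (SD, n = 3) against 11.42, and lay above background in both groups. The camera test of the list gave adjusted p = 7.18e-11, and adjusted p = 0.454 with an estimated correlation.

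The mesenchymal stromal list fell as well, with a median of -1.99 over 23 genes, 9 of which fell adjusted over the list alone. Lepr, the leptin receptor that marks perivascular stromal cells, was at 6.61 ± 0.71 (SD, n = 3) against 10.80. Ebf1 was lower by -4.34 (SE 0.30) and Lum, a matrix proteoglycan, by -4.55 (SE 0.90), and both were among the 9. Dcn, a related proteoglycan, had a difference of -4.36 (SE 1.79) and did not pass. For this list camera gave adjusted p = 1.45e-08, and adjusted p = 0.454 with an estimated correlation. Nes itself, the gene whose promoter drives the reporter, was at 4.25 ± 0.32 (SD, n = 3) against 4.26, under the background limit in both groups. Beside both lists, Ptprc, the gene of CD45, was at 10.16, 9.46 and 10.40 on the MPN arrays and 7.07 on the control array.

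Bone-forming and matrix genes fell together with the niche genes. The osteoblast list had a median of -2.04 over 15 genes, and 7 of these fell adjusted over the list alone, Phex and Col1a1 among them. Col1a1, a chain of type I collagen, was at 7.56 ± 0.12 (SD, n = 3) against 10.34. Postn, a matrix protein of periosteum, was lower by -5.20 (SE 1.39) and did not pass. The osteoblast list had adjusted p = 2.47e-10 with camera, and adjusted p = 0.328 with an estimated correlation. The fibrosis and extracellular matrix list had a median of -1.76 over 31 genes, and 13 fell adjusted over the list alone. Bgn, the proteoglycan biglycan, was among the 13 with -4.20 (SE 0.45). Mmp13 at -4.96 (SE 2.42) and Fap, a fibroblast surface protease, at -4.59 (SE 1.52) were not. The matrix list had adjusted p = 7.18e-11 with camera, and adjusted p = 0.328 with an estimated correlation. The Ptprc values given above apply to these lists too, since leukocyte genes were higher on the same arrays.

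Other stromal lineages gave no call. The median was 0.0757 over 17 chondrocyte genes, 0.102 over 15 adipocyte genes and 0.00790 over 16 smooth muscle and pericyte genes, while the mean and the test pointed lower in all 3 lists. Adjusted over each list alone, 1 chondrocyte gene fell (Col11a1, -1.52, SE 0.16), 0 adipocyte genes passed, and 3 smooth muscle and pericyte genes fell. Those 3 were Cald1 (-2.92, SE 0.40), Myl9 (-2.63, SE 0.21) and Abcc9, which was outside the naming rule and chosen after its values were seen (-1.64, SE 0.27). Adipoq, the adipocyte hormone adiponectin, had a difference of -4.76 (SE 1.06). The camera adjusted p values were 0.735, 0.352 and 0.218. The TGF-beta and BMP target list fell, with a median of -0.19 over 22 genes and 5 that fell adjusted over the list alone. Tgfbr3, a co-receptor, was at -2.83 (SE 0.28). With camera this list had adjusted p = 0.00595, and adjusted p = 0.594 with an estimated correlation. The call also ended among genes above background, where adjusted p was 0.105, and after repeated quantile normalisation, where it was 0.0852 and the median -0.0249. Over all alternatives the median of this list ran from -0.449 to -0.0249. As deposited, it lay at percentile 13.65 of random lists matched on mean expression, whose median was 0.0255. As with the niche lists, Ptprc was higher on the same arrays, by 2.94.

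Neutrophil genes rose the most of the lists tested. The list of neutrophils and granulocyte precursors had a median of 2.95 over 21 genes, and 17 of them rose adjusted over the list alone while 0 fell. Mmp8 rose by 4.77 (SE 0.41), Chil3, a chitinase-like secreted protein, by 4.37 (SE 0.74), and Ly6g, the neutrophil surface marker, by 4.31 (SE 0.87). The pan-leukocyte list had a median of 2.32 over 18 genes, and 11 rose adjusted over the list alone. Cd53 was at 11.24, 9.37 and 10.88 on the MPN arrays against 6.83, and Cd52 at 10.24 ± 0.33 (SD, n = 3) against 6.82. Ptprc, whose protein the sort selected against, rose by 2.94 (SE 0.46). For neutrophil genes camera gave adjusted p = 3.13e-12, and adjusted p = 0.538 with an estimated correlation. For pan-leukocyte genes it gave adjusted p = 1.45e-08, and adjusted p = 0.584 with an estimated correlation.

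Other blood cell lists moved less. Megakaryocyte and platelet genes rose with a median of 0.62 over 17 genes (adjusted p = 0.0119), and 0 passed adjusted over the list alone. The list gave adjusted p = 0.636 with an estimated correlation and 0.0568 without MPN mouse 3. Over the alternatives its median ran from 0.361 to 0.762. Pf4, a platelet chemokine, was at 6.84 ± 1.32 (SD, n = 3) against 5.03. T and natural killer cell genes rose with a median of 0.38 over 20 genes (adjusted p = 0.0357), of which 7 lay above background and 0 passed adjusted over the list alone. That list gave adjusted p = 0.696 with an estimated correlation, 0.095 without MPN mouse 2 and 0.249 among genes above background. Its call also ended after repeated quantile normalisation (0.0531), cyclic loess (0.0639) and the shift to one median of the receptor genes (0.0733), where the median was 0.377, 0.209 and 0.123. Ptprc was higher by 2.94 on the arrays where these 2 lists rose.

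No call was made for monocytes and macrophages (median 0.32, 22 genes, adjusted p = 0.185), which passed at 0.0482 without MPN mouse 1. Ccr2, a monocyte chemokine receptor, was at 8.51 ± 1.43 (SD, n = 3) against 5.02. Erythroid genes (median 0.27, adjusted p = 0.349), mast cell and basophil genes (0.64, adjusted p = 0.185), and stem and progenitor cell genes (0.32, adjusted p = 0.449) did not pass either. In these 4 lists 0 genes passed adjusted over the list alone. B and plasma cell genes had a median of 0.20 (adjusted p = 0.487), and the 1 that fell adjusted over the list alone was Ebf1, which is also on the mesenchymal list. Vpreb1, a gene of B cell precursors, was at 4.36, 11.26 and 4.80 on the MPN arrays and 9.64 on the control array. Endothelial genes rose with a median of 0.45 over 23 genes (adjusted p = 0.0146, and adjusted p = 0.696 with an estimated correlation). Of these, 14 lay above background, 0 passed adjusted over the list alone, and the member with the largest difference, Erg, was at 5.56 ± 0.27 (SD, n = 3) against 4.82. The median was 0.196 with the receptor gene shift, and Ptprc (2.94) and the neutrophil list (2.95) were higher on the same arrays.

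**Figure D2:**
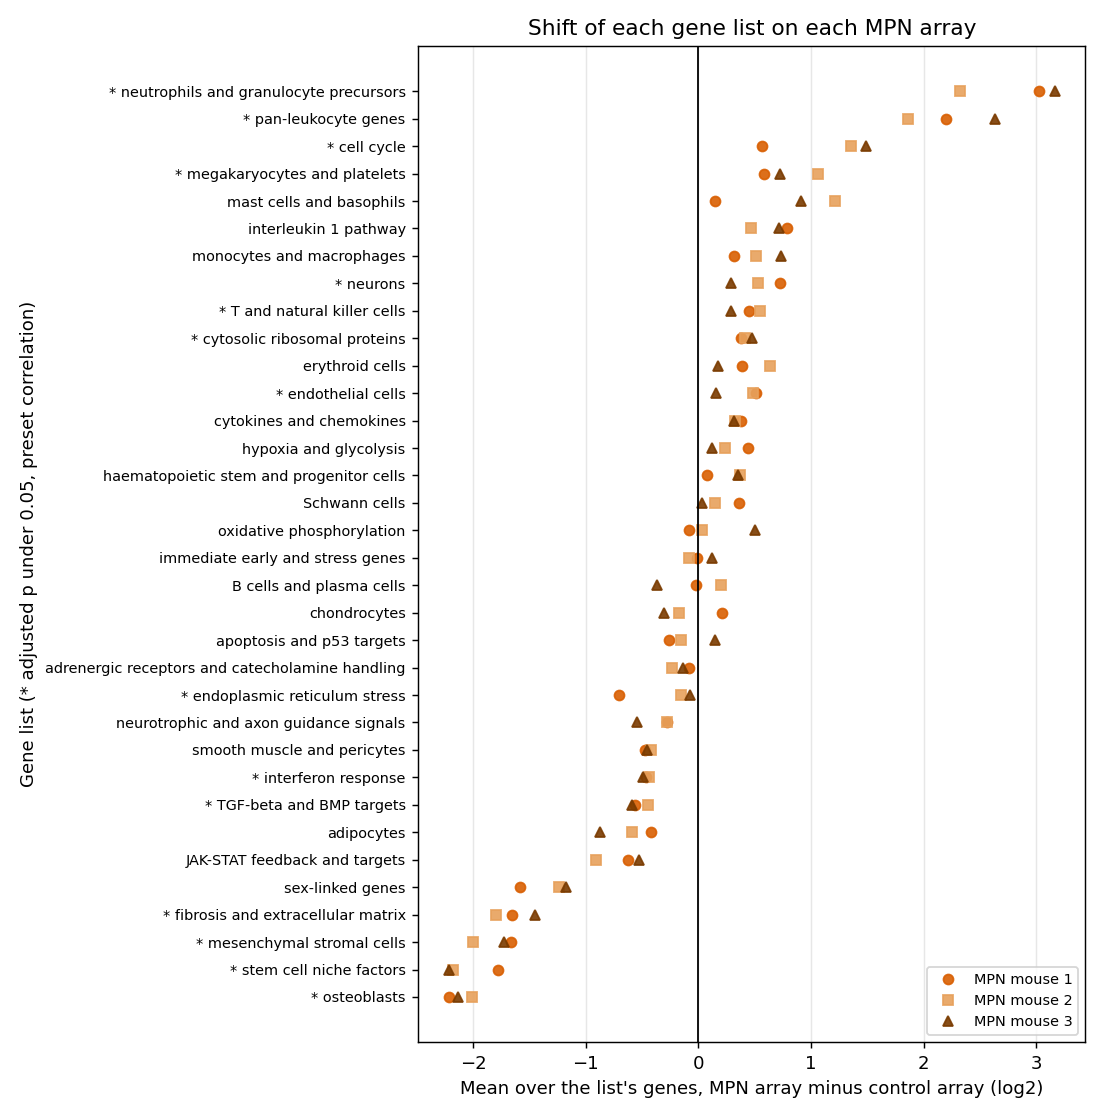
Mean difference over each list's genes (log2, horizontal axis) between an MPN array and the control array, 1 point per MPN mouse and 1 line per list; an asterisk marks an adjusted p under 0.05 with camera at its preset correlation. Neutrophil and pan-leukocyte genes lie farthest right in each mouse, and the osteoblast, niche, mesenchymal and matrix lists lie farthest left; with an estimated correlation 0 of the lists passed.

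The lists included nerve and glia genes because the study concerned nerves. The arrays hold sorted reporter cells, so these genes do not measure the nerves of the marrow. Neuron genes rose with a median of 0.46 over 21 genes, of which 11 lay above background and 0 passed adjusted over the list alone. Nefl, a neurofilament chain, was at 6.41 ± 0.53 (SD, n = 3) against 4.44, and Nefh, another chain, at 7.11 ± 0.30 against 6.14. Camera gave adjusted p = 0.01, and adjusted p = 0.696 with an estimated correlation, while Ptprc was higher by 2.94. The receptor gene shift left a median of 0.201. Schwann cell genes had a median of 0.34 over 22 genes and gave no call (adjusted p = 0.349), with 0 passing adjusted over the list alone. Members went both ways, with S100b higher by 2.84 (SE 0.66), Mbp, a myelin protein, higher by 2.34 (SE 0.33), and Egr2, a transcription factor of myelination, at -2.24 (SE 0.70). In the list of neurotrophic and axon guidance signals, the median was 0.22 over 23 genes while the test pointed lower (adjusted p = 0.596). The 2 genes that fell adjusted over the list alone were Slit2, a guidance ligand, at -4.82 (SE 0.29) and Nrp2, a semaphorin receptor, at -3.69 (SE 0.26). Of 13 adrenergic and catecholamine genes listed, 4 were measured and the list was not tested. Maob, an enzyme that degrades monoamines, was at 4.77 ± 0.50 (SD, n = 3) against 6.17, Adra2c was higher by 0.55 (SE 0.27) and Adra1b by 0.41 (SE 0.21), and 0 of the 4 passed adjusted over the list alone. Adra2c and Adra1b lay under the background limit in both groups, where the receptor genes that mark background were themselves higher by 0.254.

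Inflammatory genes went both ways. Il1b, the cytokine interleukin 1 beta, was at 10.35 ± 0.68 (SD, n = 3) against 7.39, a log2 difference of 2.96 (SE 0.62) that did not pass. The interleukin 1 list had a median of 0.42 over 15 genes (adjusted p = 0.487), with 0 passing adjusted over the list alone. Il1r2, the decoy receptor, was at 8.04 ± 1.97 (SD, n = 3) against 5.48. The cytokine and chemokine list had a median of 0.35 over 27 genes (adjusted p = 0.646). Adjusted over the list alone, 2 rose and 3 fell. The pair that rose was Lcn2, an iron-binding granule protein, by 4.23 (SE 0.75) and Cxcl2, a neutrophil chemokine, by 3.29 (SE 0.20). The 3 that fell, chosen after their values were seen, were Cxcl14 (-2.99, SE 0.53), Cxcl9 (-2.39, SE 0.31) and Saa3 (-2.24, SE 0.37). On these arrays Ptprc was higher by 2.94 and the neutrophil list by a median of 2.95. A change in cell content was therefore not separated from a change in Il1b or the other inflammatory genes.

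The interferon response list fell with a median of -0.40 over 21 genes, and adjusted over the list alone 4 fell and 1 rose. Ifit3 (-3.40, SE 0.51), Ddx58, the sensor RIG-I (-1.82, SE 0.16), and Ifit1 (-1.81, SE 0.15) fell. Outside the naming rule and chosen after their values were seen, Irf1 fell too (-1.56, SE 0.23) and Oas2 rose by 0.90 (SE 0.16). The interferon list had adjusted p = 0.0119 with camera, and adjusted p = 0.502 with an estimated correlation. After the shift to one median of the receptor genes it was 0.0669, with a median of -0.655. The median was -0.122 without MPN mouse 1 and -0.23 without MPN mouse 2. On the same arrays Ptprc was higher by 2.94 and the neutrophil list by a median of 2.95, so a change in cell content was not separated from a change in the interferon genes. In the JAK-STAT list, the median was 0.16 over 21 genes while the test pointed lower (adjusted p = 0.447). Adjusted over the list alone 1 gene fell, which was Socs2 (-1.62, SE 0.17, chosen after its values were seen), a feedback inhibitor. Lifr, the receptor of leukaemia inhibitory factor, was at -5.27 (SE 1.40) and Osmr, a related receptor, at -3.44 (SE 0.83). Jak2 was at 6.42, 4.56 and 8.14 on the MPN arrays and 8.06 on the control array, a difference of -1.68 (SE 1.59) within the spread of the MPN mice. The probes were not checked against the mutant allele.

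Cell cycle genes rose, with a median of 1.08 over 29 genes. Cdk1, the mitotic kinase, was at 8.17 ± 1.39 (SD, n = 3) against 5.57, and Ccnb2, a mitotic cyclin, at 9.52 ± 1.10 against 7.17. Adjusted over the list alone 1 gene rose, the ribonucleotide reductase gene Rrm2 (1.93, SE 0.20), which was chosen after its values were seen. Camera gave adjusted p = 0.000107, and adjusted p = 0.615 with an estimated correlation. Cytosolic ribosomal protein genes rose with a median of 0.40 over 23 genes, with 0 passing adjusted over the list alone. Rpl8 was higher by 1.20 (SE 0.21). The median lay at percentile 77.69 of random lists matched on mean expression, whose median was 0.261. Camera gave adjusted p = 0.00185, and adjusted p = 0.502 with an estimated correlation. The call ended after repeated quantile normalisation (median 0.106, adjusted p = 0.649) and after cyclic loess (median 0.0578, adjusted p = 0.288), so the size of this rise depends on the scaling. Beside these lists Ptprc and the neutrophil genes were higher on the same arrays.

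Endoplasmic reticulum stress genes fell with a median of -0.31 over 20 genes (adjusted p = 0.0395), with 0 passing adjusted over the list alone. Pdia4, a protein disulfide isomerase, was at 6.16 ± 0.63 (SD, n = 3) against 8.74. This list gave adjusted p = 0.696 with an estimated correlation, and its call held under 3 of 13 alternatives. It ended, among others, without MPN mouse 1 (median -0.0632, adjusted p = 0.187) and without MPN mouse 2 (median -0.33, adjusted p = 0.057). Ptprc was higher by 2.94 on the same arrays. The hypoxia and glycolysis list gave no call (median 0.19, 22 genes, adjusted p = 0.914). Adjusted over the list alone 2 of its genes rose, the glycolytic enzyme genes Pgk1 (9.85 ± 0.21 against 8.10) and Pkm (9.24 ± 0.14, SD, n = 3, against 7.64, chosen after its values were seen). The 1 that fell was Bnip3 (-1.25, SE 0.19, chosen likewise). Oxidative phosphorylation genes (median 0.13, adjusted p = 0.603), apoptosis and p53 target genes (0.0579, adjusted p = 0.593) and immediate early and stress genes (0.0133, adjusted p = 0.487) gave no call. In these 3 lists 0 genes passed adjusted over the list alone, and in the last 2 the test pointed lower against a median above 0.

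Of the 32 lists tested, camera called 8 higher and 7 lower at its preset correlation. With an estimated correlation 0 were called, and the smallest adjusted p was 0.328, while 3 lists had an unadjusted p under 0.05. Among 10000 random lists matched on mean expression, the medians of the neutrophil, pan-leukocyte and cell cycle lists lay at percentile 100. Those of the niche, mesenchymal, osteoblast and matrix lists lay at percentile 0. Of the other called lists, megakaryocyte (99.98), endothelial (99.82), neuron (99.72), T and natural killer cell (98.0) and interferon genes (0.03) lay near the ends. Some lists without a call lay near the ends too, namely mast cell and basophil (99.99), interleukin 1 (98.04) and cytokine genes (97.22). The medians of endoplasmic reticulum stress (4.43), TGF-beta and BMP target (13.65) and ribosomal protein genes (77.69) lay within the range that random lists span. The random lists were drawn gene by gene, so they lack the correlation between genes of a real list, estimated at 0.424 for neutrophil genes. Their medians vary less for that reason, and the percentiles describe the lists without testing them. With fry 3 of the 15 passed, namely osteoblasts (0.0278), matrix genes (0.0236) and the interferon response (0.0236).

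Sex-linked genes separated the control array from the MPN arrays. Xist was at 8.37, 9.31 and 9.22 on the MPN arrays and 3.30 on the control array. The Y-linked genes Eif2s3y, Kdm5d and Uty were lower by -4.32 (SE 0.40), -3.56 (SE 0.15) and -3.10 (SE 0.19). All 3 lay under the background limit on each MPN array and above it on the control array. Adjusted over the list alone, 1 of the 4 measured genes rose and 3 fell. Sex and group cannot be told apart here, and this holds for each gene and list above. Setting each array in turn against the other 3, the number of genes at least 2-fold apart was 629 for MPN mouse 1, 685 for MPN mouse 2, 388 for MPN mouse 3 and 1378 for the control.

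**Figure D3:**
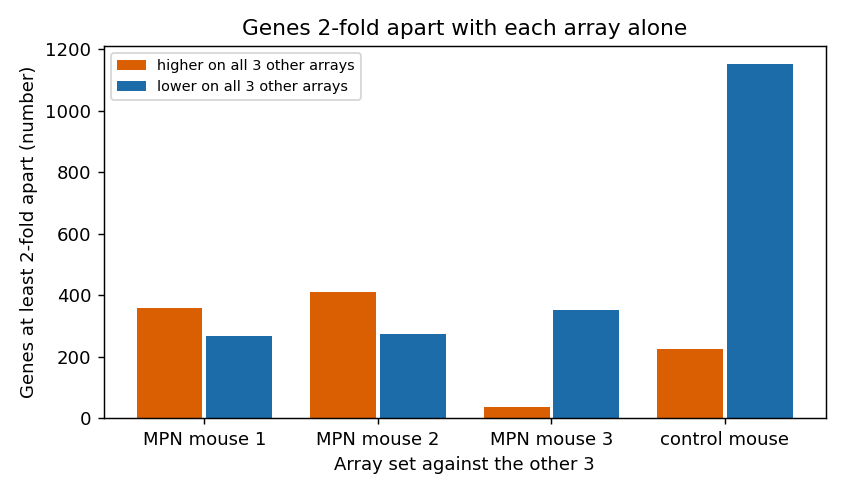
Number of genes at least 2-fold higher or lower on all 3 other arrays (vertical axis), with each array alone in turn (horizontal axis). The control has 1153 genes lower and 225 higher on the others, and the MPN mice total 388 to 685.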

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

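Shifting the arrays to one median of the receptor genes was chosen after seeing the data, and the other alternatives before. The count of genes past the threshold stayed at 0 except with cyclic loess (97, of which 4 higher and 93 lower) and with that shift (153, of which 7 higher and 146 lower). These settings moved the median difference of all genes from 0.179 to 0.0121 and -0.0779, and the smallest adjusted p to 0.048 and 0.0464. Over the other alternatives the smallest adjusted p ran from 0.0572 to 0.454. The count of 0 with 1 MPN mouse left out rests on fewer residual degrees of freedom and says little about stability. At an unadjusted p under 0.05 the count was 2511 as deposited and 1757, 1886 and 3753 without MPN mouse 1, 2 and 3. Genes 2-fold apart on each MPN array numbered 1685 to 2134 with 1 mouse left out, 373 to 378 of them higher and 1312 to 1756 lower. These counts grow in part because fewer arrays must meet the condition, and leaving out MPN mouse 3 gave the largest total (2134). The share of lower genes was 83.7% as deposited, 77.8% without MPN mouse 1, 79.4% after repeated quantile normalisation and 91.1% with the receptor gene shift. Lists called numbered 13 to 15 with 1 mouse left out, 0 with an estimated correlation and 3 with fry. The estimated correlation was -0.00778 for the matrix list and 0.00467 for osteoblasts, under the preset 0.01. It was higher for others, such as neutrophil genes (0.424). Each correlation was estimated from 2 residual degrees of freedom. A higher correlation between genes therefore does not account for the loss of the matrix and osteoblast calls. The tests also differ in degrees of freedom, 2 with an estimated correlation and set by the number of genes with the preset one. With 2, a call is hard to reach, so 0 calls neither upholds nor refutes the preset calls. How much each difference contributed in the other lists was not tested.

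Over the alternatives, 359 of 416 list results kept direction and side of the threshold, 46 lost a call and 1 gained one. Of the 1444 results for named genes, 1413 kept both and 28 passed the threshold, all under cyclic loess or the receptor gene shift. The test of 6 lists turned direction, with no call, and medians are given for these. For hypoxia and glycolysis it turned without MPN mouse 1 or 3 (0.204 to 0.268 with 1 mouse left out) and with a variance trend (0.195). For chondrocytes it turned without MPN mouse 3 (0.015 to 0.0938 with 1 mouse left out) and after repeated quantile normalisation (0.152). Without MPN mouse 3 it turned for neurotrophic and guidance signals (0.152 to 0.321) and for oxidative phosphorylation (0.00446 to 0.302). Immediate early genes turned above background and with fry (0.0133 in both), and apoptosis genes with fry (0.0579). Among named genes with 1 mouse left out, the difference ran from -1.299 to 0.0984 for Pdia6, which turned without MPN mouse 1. It ran from -0.02099 to 2.035 for Car2 and from -0.1678 to 0.148 for Nes, both of which turned without MPN mouse 2. The cause was not tested. Repeated quantile normalisation moved values by up to 0.286. No paired analysis was possible because the control group has 1 mouse, which shares no pairing with the MPN mice. Signal over background was the narrowest, among the lists called, for T and natural killer cells, with 7 of 20 genes above the limit.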

Other observations

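The gene families here were chosen after the values were seen, and so were the tests of explanations, except the one on unseen members of the myelin list. Families were picked because members were among the largest differences, so their counts describe those differences and carry no test. Of 26 histone genes used in DNA replication, 10 were at least 2-fold higher on each MPN array and 1 was lower (215 of 19912 other genes were higher), with a median of 1.33. H4c6, a histone H4 gene, was at 7.52, 10.48 and 7.87 against 4.42, although near-identical histone copies can share probes. C-type lectin genes of the Clec family had 4 of 33 members higher (221 of 19905 other genes) and a median of 0.334, which fell to 0.0774 with the receptor gene shift. Among them, Clec4e, a receptor of myeloid cells, was at 9.55 ± 1.33 (SD, n = 3) against 5.70. Of 7 insulin-like growth factor binding protein genes, 4 were at least 2-fold lower (1149 of 19931 other genes), with a median of -1.76, namely Igfbp3 (-1.76), Igfbp4 (-2.13), Igfbp5 (-3.31) and Igfbp7 (-3.33). Collagen genes had 7 of 44 lower (1146 of 19894 other genes), and semaphorin, plexin, slit and robo genes 6 of 36 (1147 of 19902). The medians of these 2 families were 0.0657 and 0.116 as deposited, and -0.0282 and -0.0906 after cyclic loess, so no direction is given for them.

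The first pattern joins higher neutrophil and pan-leukocyte genes with lower stromal genes, and a higher background of the MPN arrays is argued against, since the smaller of the lists' medians exceeded the shift of the receptor genes by 2.06. Leukocyte RNA in the MPN sorted cells is a candidate explanation. Ptprc was at least 2.4 higher on each MPN array although the sort selected against CD45, and Ltf and Camp, abundant neutrophil genes, reached 11.32 and 11.63. The control array carried leukocyte genes above the background limit too, with Ptprc at 7.07 and Vpreb1 at 9.64. Against one dilution factor for stromal RNA, Col1a1 (-2.78, SD 0.12) and Phex (-5.64, SD 0.24) differed beyond their spread, and 5 stromal genes that went under the background limit were lower by 4.34 to 6.12. It stays open because those 5 are near the floor and among the pattern's largest differences: all 16 stromal genes off the background had a range of 4.36, past the bound of 2.99 (4 times the median SD), but the 10 of them that other marrow cells are not known to use, picked afterwards, had 1.81, under their bound of 2.47, and 3.35 with 3 such genes under the limit added, past 2.25. Sex of the mice stays open, since 0 MPN arrays carried a Y-linked gene above background, and so does a biological effect of the MPN marrow on the niche, which cannot be told apart from these with 1 control.

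The second pattern is a group of genes, several of them known from myelinating glia, that were higher on each MPN array and picked after their values were seen: Plekhb1 (5.05), Ermn (3.99), Mobp (3.91), Bcas1 (3.91), Pkp4 (3.75), Gjc3 (3.66) and Trak2 (3.24). Intact oligodendrocytes are argued against by abundant transcripts of theirs, chosen afterwards: Mog, Mag, Cnp and Cldn11 were higher by 0.411 at most, the first 2 of them with an MPN mean under the background limit. For Schwann cells, the median over the 22 genes of their fixed list was 0.336. It lay 2.9 below the smallest rise of the group, more than 2 times the SD of the list's members (1.13). This bound was set after the values were seen and rests on genes picked for their rise. Of the 22, 13 lay above the background limit, with a median of 0.363. S100b (2.84) and Mbp (2.34) were higher, though neither passed adjusted over the list alone. Set against genes picked for their rise, the median cannot decide on Schwann cells, which stay open. RNA of the kind found in purified myelin, without its cells, was tested on 7 list members not looked at before, with a median above 1 needed for it and under 0.5 against it. The median was 0.698, between these bounds, with Dync1li2 higher by 1.91 and Bace1 at -0.85, so this explanation may hold and stays open.

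The third pattern is sex. A candidate explanation is that the MPN arrays hold RNA of female cells and the control array RNA of male cells: all 3 Y-linked genes were above background on the control array and under it on each MPN array, with Xist the other way. Whether this is the sex of recipients, donors or both was not tested. For the count of genes 2-fold apart, 1 of the 4 splits of the arrays into 3 and 1, the real one, gave as many as 1378, and the highest other gave 685. So few splits cannot give a share under 0.05.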
